A study of Salmo salar with 8 samples.

How the data were processed

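The data were 8 one-colour (Cy3) Agilent arrays of Salmo salar head kidney RNA, 2 for each phenotype at 1 and 5 days after infection. Labelled RNA came from pools within families, per the labels' protocols. The spot values are intensity values on a linear scale that Agilent Feature Extraction wrote, per the file headers, with background subtraction and no scaling between arrays. The software version is 10.1.1.1 per the file headers and 10.4.0.0 per the submitters' processing notes, and the difference was not resolved. The authors' deposited value table holds log2 values that equal the log2 of each spot's background-subtracted signal to within 5e-09, with no scaling between arrays and with blanks where that signal was not above 0. Its array medians were 9.11, 8.02, 6.94, 7.05, 9.10, 8.02, 8.57 and 7.18 for families 5352, 5469, 5459, 5761, 5629, 5637, 5463 and 5764.

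The log2 of the processed signal was taken with R 4.3.3, the 1417 control spots of each array were left out, and the array's 75th percentile was subtracted. Because 47.7% of non-control spots were well above background on all 8 arrays, under the 50% limit fixed before the data were examined, the percentile was taken over those 20034 spots. That limit can also be read as applying to each array, where it is not met, so the percentile over all non-control spots was run as an added alternative. Spots with a non-uniformity or population outlier flag, 931 over all arrays, were left out and saturated spots were kept. Both spots of a probe were averaged. A probe was tested if it had a value on all 8 arrays and was well above background on both arrays of at least 1 group, which 15421 of 21012 probes met. Well above background was taken to mean both spots of the probe. This definition was settled after a first look at the values with a definition of at least 1 spot, which is given as an alternative.

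Limma 3.58.1 fitted 1 mean per group on all 8 arrays, with the eBayes defaults and Benjamini-Hochberg adjustment within each of 6 contrasts at a threshold of 0.05. Arrays are separate families and not separate fish, so p-values measure the spread between family pools, taken as equal in the groups fitted. For a probe not well above background on any array of a group, the fold is a bound: the bright group's mean log2 value against the dim group's mean of, per array, the higher of the probe's value and the lowest value among probes well above background. Resistant and susceptible arrays were compared within each slide. Each slide held 1 day, so that slide cannot be told apart from day. Susceptible arrays lay at positions 1 and 2 and resistant arrays at positions 3 and 4 of both slides, so that position and phenotype cannot be told apart.

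None of the 21012 probe identifiers matched an accession, symbol or synonym among 65341 genes of the reference table (assembly Ssal_v3.1), and the files do not pair identifiers with gene names. The gene lists and cell type markers fixed before the data were examined were therefore not used here. The rule for named genes, fixed at the same time, falls back to identifiers: with no probe past the threshold, the probe of smallest unadjusted p in each direction with an absolute log2 difference of at least 1 and no overlap between the arrays compared, in each within-day contrast. At most 2 identifiers in each direction are printed.

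The fit was tested on simulated data for 15421 probes with the fitted spread, independent errors and 200 changed probes. For resistant against susceptible families over both days, 54.0% of 50 probes changed by 4 on the log2 scale were recovered, 26.0% of those changed by 3, 4.0% of those changed by 2 and 0 of those changed by 1. For each of the other 5 contrasts 0 of 50 were recovered at each of these sizes. The fitted spread is a single value per probe for all groups, but the array pairs within groups differed in spread. Within the resistant pairs 20.7% and 23.9% of probes differed at least 2-fold, against 51.9% and 65.1% within the susceptible pairs. The recovery rates therefore hold for a spread equal in all groups, and recovery at the spread of the resistant families alone was not tested. With the spread divided by 10, 78.0% to 96.0% of probes changed by 1 were recovered over the 6 contrasts.

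Alternatives fixed before the data were examined were quantile normalization, median scaling, no filter on dim probes, a filter for all 8 arrays, outlier-flagged spots kept, the deposited log2 values with the same scaling, trend and robust variance, only the 4 arrays compared, no day block, and leaving out each array. Chosen after seeing the data were normexp with an offset of 50 on the median signal in place of the mean signal, the percentile over all non-control spots, detection by at least 1 spot, no scaling, 4 spike-in scalings, leaving out both arrays of each slide position, and slide position as a block for the contrasts between days. The first spike-in scaling took the median of 5 unsaturated spike-in probes. The second took the mean of the other 4, without E1A_r60_3, and was added once the first had been run, because on the arrays of families 5352 and 5629 that median was E1A_r60_3 itself. The mean of 5 and the median of 4 were added so that the probe and the kind of average are changed one at a time.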

Results

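Head kidney RNA of Atlantic salmon (Salmo salar) fry was measured after a bath challenge with infectious pancreatic necrosis virus, a virus that causes mortality in farmed salmonids. The head kidney is a blood-forming and lymphoid organ of fish. Families labelled susceptible or resistant to the virus were sampled 1 day and 5 days after infection. Each of the 8 arrays held RNA pooled within 1 family, with 2 arrays in each of the 4 groups of phenotype and day. The series' design text gives n = 2 for each susceptible family and n = 3 for each resistant family, which is read here as fish per pool. All 8 families differed, and no uninfected fish were analysed here. Each array had 42024 spots for 21012 probes, and 15421 probes were tested. Between 52.8% (family 5637) and 80.7% (family 5469) of the spots were well above background. The number of arrays and the spread between families limit the precision: the median residual SD was 0.83 on the log2 scale, with 4 residual degrees of freedom. This SD is pooled over the 4 groups. The susceptible pairs were further apart than the resistant pairs, as given next, so that it is not the spread of either phenotype alone.

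The first question was how alike the families of 1 group were. At 1 day, resistant families 5459 and 5761 correlated at r = 0.957 across the tested probes, and 20.7% of probes differed at least 2-fold between them. At 5 days, resistant families 5463 and 5764 correlated at r = 0.931, with 23.9% of probes differing at least 2-fold. The susceptible families were further apart. Families 5352 and 5469 at 1 day correlated at r = 0.825, with 51.9% of probes at least 2-fold apart. Families 5629 and 5637 at 5 days correlated at r = 0.743, with 65.1% of probes at least 2-fold apart. These correlations are across probes, which are not independent replicates.

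Susceptible families 5352 (1 day) and 5629 (5 days) resembled each other more than the other family of their own group. They correlated at r = 0.952 with each other, and at r = 0.713 to 0.857 with the other 6 arrays. Those 6 arrays, of both phenotypes and both days, correlated at r = 0.888 to 0.962 with one another. The first principal component held 61.5% of the variance and separated families 5352 and 5629 from the rest. Both arrays lay at position 1 of their slide and were the brightest, with 75th percentiles of 3387 and 2818 against 576 to 1567 on the other 6.

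**Figure D1:**
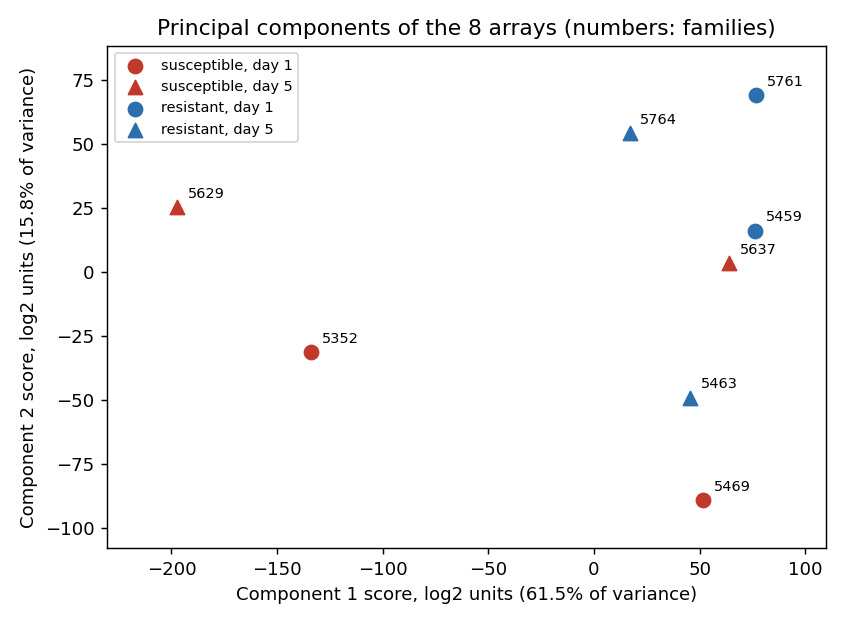
Scores of the 8 arrays on the first and second principal components of the scaled log2 values of 15421 probes, coloured by phenotype with a symbol for the day and labelled by family. Families 5352 and 5629 lie at -134.0 and -197.5 on the first component, and the other 6 arrays lie between 16.8 and 76.7.

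Resistant and susceptible families were then compared at 1 day, when both groups lay on 1 slide. No probe passed an adjusted p of 0.05 in limma, and 948 probes had an unadjusted p under 0.05 (632 higher and 316 lower in resistant families), where 771 are expected by chance. Without the filter on dim probes 2176 of 21004 probes did (1864 higher and 312 lower), and with normexp background correction 1622 did (1534 higher and 88 lower). The split was 468 and 115 among the 9597 probes well above background on all 8 arrays, and 1112 and 800 with only the 4 arrays compared. With no scaling it was 16 and 3656, and the median difference of all probes was -1.85. Unscaled values keep array brightness, with 75th percentiles of 3387 and 1539 in susceptible and 642 and 576 in resistant families. The split of probes at an unadjusted p under 0.05 differed when 1 of the 4 arrays compared was left out. It was 90 higher and 291 lower without family 5352, 651 and 582 without 5469, 500 and 74 without 5459, and 44 and 128 without 5761. It was 1230 and 1190 without 5629 or without 5637, which enter this contrast only through the shared spread. Which probes these counts share was not examined. With limma's trend and robust options the counts were 0 and 860. The smallest adjusted p was 0.642. All resistant arrays lay above all susceptible arrays for 25.5% of probes and below for 26.4%, where chance gives 16.7% each way. Probe Omy#CB490338, which the files do not pair with a gene name, was at 4.87 ± 0.18 in resistant and 1.96 ± 0.10 in susceptible families (log2 relative to the array's 75th percentile, SD, n = 2). Its log2 difference was 2.91 ± 0.54 (SE), with an adjusted p of 0.642 in limma. Probe Ssa#S32011714 was at -7.48 ± 0.50 in resistant and -3.73 ± 0.65 in susceptible families (SD, n = 2). Its log2 difference was -3.75 ± 0.62 (SE), with an adjusted p of 0.642 in limma. It was not well above background on both spots on either resistant array, so that it was at least 6.23-fold lower on these arrays. This bound holds for the processed signal: normexp background correction with its offset of 50, chosen after seeing the data, gave a log2 difference of -1.23.

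The median 95% interval of a log2 difference at 1 day was 1.88 either way. The count of 0 depended on the scaling and on the arrays, in fits chosen after seeing the data. Scaling to the median of 5 unsaturated spike-in probes gave 2171 probes, of which 2170 were lower in resistant families, and scaling to their mean gave 0. Without spike-in probe E1A_r60_3 the mean of the other 4 gave 861 and their median 769, all lower in resistant families. The median difference of all probes moved from -0.04 to between -2.25 and -2.78 under these scalings, and that of Omy#CB490338 from 2.91 to between 0.16 and 0.69. Without the arrays of slide position 2, which left family 5352 as the only susceptible array at 1 day, 2302 probes passed.

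The same comparison at 5 days, on the other slide, gave 0 probes past the threshold in limma and 406 at an unadjusted p under 0.05, of which 347 were higher and 59 lower in resistant families. This split was 2671 and 1670 without family 5637, 155 and 136 without 5629, 149 and 19 without 5764, and 213 and 30 without 5459 or without 5761. It was 1570 and 6 with normexp, 277 and 124 with quantile normalization, and 195 and 108 with median scaling. With no scaling, which keeps array brightness, it was 47 and 80, and the median difference of all probes was -0.67. The 9597 probes well above background on all 8 arrays gave 200 and 27, and a fit of only the 4 arrays compared gave 198 and 30. Scaling to the median and mean of 5 spike-in probes gave 62 and 32, and 30 and 44, and the mean and median of 4 gave 7 and 76, and 7 and 87. With trend and robust options the counts were 0 and 375. The smallest adjusted p was 0.880. Resistant arrays lay above susceptible arrays for 17.5% of probes and below for 9.12%, where chance gives 16.7% each way. Probe Ssa#S18878653 was at 2.20 ± 0.61 in resistant and -2.89 ± 0.46 in susceptible families (SD, n = 2), a log2 difference of 5.09 ± 0.75 (SE) with an adjusted p of 0.880 in limma. Probe Ssa#DY704437 was at -6.90 ± 0.49 in resistant and -2.25 ± 0.14 in susceptible families (SD, n = 2). Its log2 difference was -4.65 ± 0.85 (SE), with an adjusted p of 0.880 in limma. It was not well above background on either resistant array, so that it was at least 12.8-fold lower on these arrays. This bound too holds for the processed signal, as normexp gave a log2 difference of -1.35. No probe passed under any of the 4 spike-in scalings, and 4458 passed without the arrays of slide position 2, which left family 5629 as the only susceptible array.

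**Figure D2:**
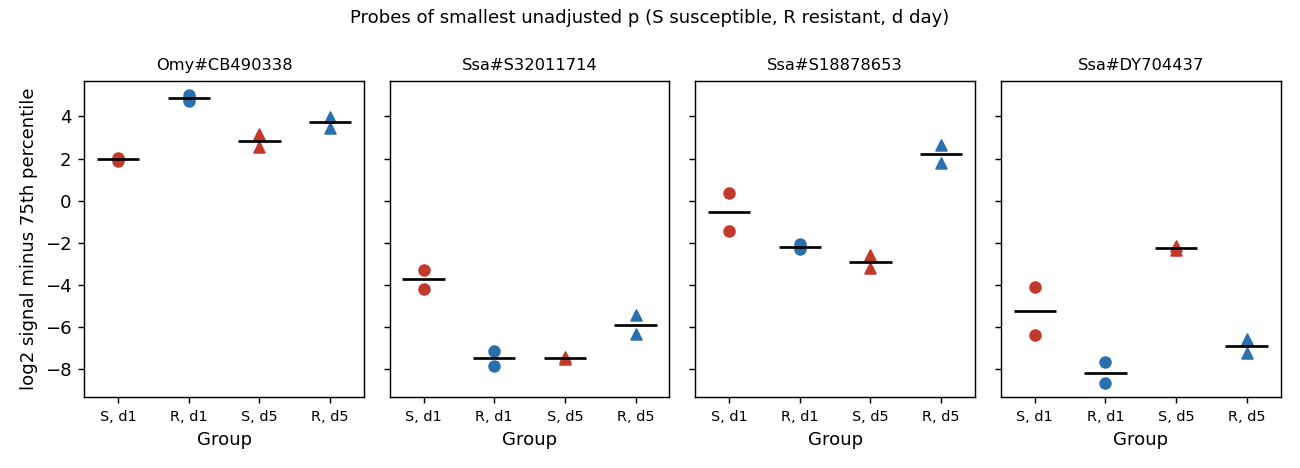
Log2 signal relative to the array's 75th percentile for 4 probes without gene names; points are arrays (1 family each), bars are means of 2 arrays, S is susceptible, R resistant, d1 day 1 and d5 day 5. Ssa#S18878653 lies at 1.77 and 2.63 in the resistant families at 5 days and between -3.21 and 0.38 in the other 6.

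Over both days together, with the day as a block, 4 resistant arrays were set against 4 susceptible arrays. No probe passed the threshold in limma, and 1153 had an unadjusted p under 0.05 (834 higher and 319 lower in resistant families). With trend and robust options these counts were 0 and 1081. This split was 1783 and 323 without the filter on dim probes (21004 tested), 1237 and 608 with no day block, 3919 and 38 with normexp, and 603 and 523 with median scaling. With no scaling, which keeps array brightness, it was 14 and 3698, and the median difference of all probes was -1.20. Of the 9597 probes well above background on all 8 arrays, 692 had an unadjusted p under 0.05, of which 587 were higher. The 771 expected by chance is for 15421 probes and does not apply to these. Without family 5352 or 5761 higher and lower probes were nearly even, and without the arrays of slide position 1 most were lower. Leaving out any other single array kept more probes higher than lower. All 4 resistant arrays lay above all 4 susceptible arrays for 344 probes and below them for 314, where chance gives 220 each way. The unadjusted count moved with single arrays: it was 260 without family 5352, 2028 without family 5469, 501 without family 5629, 683 without family 5459, 252 without family 5761, 247 without family 5764, 1036 without family 5463 and 5969 without family 5637. Without both arrays of slide position 1, 2, 3 or 4 it was 708, 8916, 723 and 54, where chance gives 771. Without position 2, 7379 probes passed the threshold. The median and mean of 5 spike-in probes gave 521 and 0 probes past the threshold, and the mean and median of the 4 without E1A_r60_3 gave 543 and 627.

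Whether the difference between phenotypes at 1 day returned at 5 days was examined across probes, since the 2 contrasts share no array. The log2 differences correlated at r = 0.45 (Spearman 0.52), and 72.5% of probes had the same sign. At least 2-fold differences at both days numbered 1197 higher and 1000 lower in resistant families, against 637 and 320 expected of independent lists, and 419 probes differed at least 2-fold in opposite directions. No probe passed the threshold at both days in limma. Of the named probes, Ssa#S32011714 (-3.75 and 1.59) and Ssa#S18878653 (-1.66 and 5.09) changed sign between 1 and 5 days. Omy#CB490338 (2.91 and 0.87) and Ssa#DY704437 (-2.95 and -4.65) kept theirs. The correlation was 0.64 without family 5469, -0.29 without family 5629 and 0.0004 without family 5352. It was -0.15 without both arrays of slide position 1 and 0.78 without both of position 2. The agreement thus rested on families 5352 and 5629, of which 1 enters each contrast. It does not show that a phenotype difference shared by the families returned.

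The change of the phenotype difference from 1 to 5 days gave 0 probes past the threshold in limma and 320 at an unadjusted p under 0.05, with 0 and 315 under trend and robust options. For Ssa#S18878653 this change was 6.75 ± 1.06 on the log2 scale (SE), with an adjusted p of 1.00 in limma. The unadjusted count ranged from 145 to 1452 over the fits without 1 array, and was 1828 with slide position as a block. Scaling to the median of 5 spike-in probes gave 16 probes past the threshold, and the other 3 spike-in scalings gave 0.

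The days were compared within each phenotype. Each slide held 1 day and the families differed between days, so that day, slide and family cannot be told apart. In susceptible families no probe passed in limma and 296 had an unadjusted p under 0.05, with 0 and 268 under trend and robust options. In resistant families no probe passed in limma and 246 had an unadjusted p under 0.05, with 0 and 213 under trend and robust options. A fit of only the 4 arrays compared gave 1578 such probes in resistant families (891 higher and 687 lower at 5 days), where 771 are expected by chance. It gave 168 in susceptible families, and no probe passed in either. Arrays at 5 days lay above those at 1 day for 781 probes in susceptible and 3633 in resistant families, and below for 1558 and 3305, where chance gives 2570 each way. Leaving out 1 array moved the unadjusted count to between 68 and 1725 in susceptible and between 82 and 477 in resistant families. Arrays at 1 slide position share a phenotype and differ in day: with position as a block, a fit added after seeing the data, the unadjusted counts were 1598 in susceptible and 1700 in resistant families, and no probe passed in limma. Past the threshold in susceptible and resistant families were 20 and 5 probes with scaling to the median of 5 spike-in probes, 0 and 0 with their mean, 1 and 3 with the mean of 4, and 1 and 2 with the median of 4.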

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

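The tests of array brightness and slide position for families 5352 and 5629, of brightness for the small p values, of mean levels of neighbouring identifiers, and of leaving out slide positions 1, 2, 3 and 4 were chosen after the results were seen. Groups of 2 arrays are too small for a search for outlying samples within a group, and with the 75th percentile scaling no probe passed the test of a different phenotype effect at 1 and 5 days (16 passed with scaling to the median of 5 spike-in probes).

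A signal outside the comparisons stood out among the spike-in control probes, synthetic targets added to each labelling. E1A_r60_3 was at 10.85 (log2 processed signal) on the array of family 5352 and 11.15 on that of family 5629, against 7.84 to 8.82 on the other 6 arrays. These values lay 7.58 and 7.41 above the median negative control spot of the same array. The mean of the other 4 unsaturated spike-in probes was 11.30 and 11.07 on those arrays and 11.19 to 12.35 on the other 6.

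Families 5352 and 5629, of different days and slides, stood apart from the other 6 arrays. Brightness as a monotone change of scale is argued against, since it leaves ranks as they are: the highest rank correlation of either array with the other 6 was 0.850, below the lowest among those 6 (0.879). An effect of slide position 1 remains open. On both slides 2 of 5 unsaturated spike-in probes lay outside the range of the other 6 arrays, and position cannot be told apart from family. The susceptible arrays at position 2 lay among the resistant arrays on the first component, at 51.8 and 64.1. A different RNA composition, such as other cells in the pools, also remains open: neighbouring identifiers on the array with the lower value correlated at 0.023, but their mean levels did not correlate beyond permutation either (0.050 against a highest permuted 0.089), so that this test was void. A biological difference between the families is untested.

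The resistant against susceptible comparison over both days gave 1153 probes at an unadjusted p under 0.05, more than the 771 expected. Chance cannot be excluded: 9 of the 34 splits of the 8 arrays that leave both days on both sides, the real one included, gave as many, and the highest other gave 3839. The largest counts put families 5352 and 5629 on 1 side. They came from splits of 3 arrays against 1 within each day, unlike the real split. Family 5629 was then alone on its side at 5 days and added no spread. Among splits of 2 against 2 within each day, like the real one, the highest count was 2521, and 2226 and 1494 also lay above 1153. Chance is therefore not excluded among these splits either. Splits with both families on 1 side also gave 249 and 200, so that the splits do not settle the part of these families. The splits by slide position gave 1494 (1 and 4 against 2 and 3) and 200 (1 and 3 against 2 and 4). Without the arrays of slide position 1 the count was 708, below chance, and it was 8916 without position 2, 723 without position 3 and 54 without position 4. Fits without position 3 or 4 take their spread from the susceptible pairs alone, which hold the position 1 arrays. The fit without position 1 takes its spread from the resistant pairs alone, with 1 susceptible array left at each day. Within each day its count lay above that of the fit of all 8 arrays, and not below chance. The counts without a slide position therefore leave the part of position 1 open. After quantile normalization the count was 1135. This leaves brightness open, because the first component of the 6 arrays at slide positions 2 to 4 still followed brightness after it. That relation was not examined over all 8 arrays.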

How the results depend on the processing

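The spike-in scalings, normexp, the slide position block and the fits without both arrays of a slide position were chosen after seeing the data. Each alternative fixed before the data were examined gave 0 probes in each contrast it applied to, as did normexp, no scaling, and the slide position block for the contrasts between days. Scaling to the median of 5 spike-in probes gave 2171 probes at 1 day, 521 over both days, 16 for the change between days, 20 for the days in susceptible and 5 in resistant families. The mean of 5 gave 0 in all 6 contrasts. The mean of 4, without E1A_r60_3, gave 861, 543, 0, 1 and 3, and the median of 4 gave 769, 627, 0, 1 and 2. All 4 gave 0 at 5 days. Spike-in calls thus changed with the kind of average and with the probe, and they take the spike-in amounts as equal. Without the arrays of slide position 2, 2302 probes passed at 1 day, 4458 at 5 days and 7379 over both days. That fit had 2 residual degrees of freedom, both from resistant arrays, and families 5352 and 5629 were its only susceptible arrays, so that it holds no spread between susceptible families. Normexp was run on the median signal, so that it changed the signal as well as the background correction. With it the median of all probes at 1 and 5 days was 0.40 and 0.74. Over both days 3919 of 3957 unadjusted calls were then higher in resistant families.

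The correlation of the 1 and 5 day contrasts ranged from -0.29 to 0.64 over the fits without 1 array, and was -0.15 without the arrays of slide position 1 and 0.78 without those of position 2; the cause was not tested. Where 1 array was left out, the remaining array of its group was assumed to vary like the other groups. Unadjusted counts over those fits ranged from 172 to 2420 at 1 day, 168 to 4341 at 5 days and 247 to 5969 over both days. Each of the 4 named probes kept its sign under each alternative that gave it a value, but not its size: Omy#CB490338 at 1 day fell to 0.16 (median of 4 spike-in probes), and normexp gave -1.23 for Ssa#S32011714 at 1 day and -1.35 for Ssa#DY704437 at 5 days. Ssa#S32011714 passed under 3 of the spike-in scalings, and all 4 probes passed without the arrays of slide position 2. The gene list alternatives and the mean over probes of 1 gene were not run, since probes carry no gene names, and normexp on mean signals was not run. Dim probes limit what can be seen: 9597 probes were well above background on all 8 arrays.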

Other observations

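The test of phenotype for the first component, the identifier classes and the spike-in comparison were chosen after the results were seen.

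Probes whose identifiers start with Ssa passed the detection filter more often than those starting with Omy, at 77.5% of 17607 against 52.2% of 3405. Of 19 identifier classes with at least 100 probes, camera with a preset correlation of 0.01 gave 6 past an adjusted p of 0.05 at 1 day and 2 at 5 days. With an estimated correlation 0 passed, with lowest adjusted p of 0.807 and 0.971.

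The gap between salmon signal and spike-in signal differed between arrays at both days, and it separated the phenotypes only at 1 day. The 75th percentile of salmon spots minus the mean of 4 unsaturated spike-in probes was 2.28 and 0.92 (log2) in the susceptible and -0.98 and -1.25 in the resistant families. At 5 days it was 2.28 and 0.07 in the susceptible and 1.35 and -0.87 in the resistant families.

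Among the 6 arrays at slide positions 2 to 4, the first component (40.8% of their variance) followed array brightness, the log2 75th percentile. Pearson's r was 0.930 (exact permutation p = 0.0042) and Spearman's rho 0.943 (exact permutation p = 0.017) in two-sided tests. This was 1 relation under 2 normalizations. The p-values were not adjusted for the choice of arrays, component and kind of correlation from the same data. Without the 2 arrays farthest from the median brightness r was 0.79 over 4 arrays (exact permutation p = 0.042, the smallest that 4 arrays can give), and 0.73 after quantile normalization (exact permutation p = 0.21). Each slide held 3 of these arrays, and their order by the component was that by brightness on both slides. With slide means taken out r was 0.973, with an exact permutation p of 0.028 over 36 orderings within slides, the smallest they can give. Monotone differences of scale are argued against, since the rank correlation was 0.943 after quantile normalization. Resistance as the cause would put both susceptible arrays at 1 end, apart from the resistant arrays. This was not seen: 1 resistant array (family 5463, at 50.8) lay between the 2 susceptible arrays (-0.7 and 89.6). The other 3 lay below both. Since the overlap rests on 1 array, a part of resistance stays open. RNA amount, labelling yield and family are open and untested.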
